A study of Mus musculus with 9 samples.

How the data were processed

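The series holds 9 RNA sequencing libraries from C57BL/6 mouse bone marrow cells, in 4 groups that combine the population (LSK or MP) with the RNA fraction (total or polysomal). Per the labels' protocols, cells were treated with 100 ug/ml cycloheximide for 10 min, which holds ribosomes on their messages, and lysates were run on 10 to 60% sucrose gradients collected in 10 fractions. Fraction 7 served as polysomal RNA, and total RNA was set aside from the lysate ahead of the gradient. RNA was extracted with Trizol and amplified with a SMARTer kit, per the labels' protocols. Sample groups and library numbers were taken from the sample titles.

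The authors deposited a table of raw counts per gene symbol, whole numbers that sum to between 27342343 and 34807735 per library. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2, and the genome builds mm10 and GRCm38. Their versions, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes and of near-identical copies, such as histone, immunoglobulin and ribosomal protein genes and their pseudogenes, may be split or merged. The authors also deposited a table of normalized values on a log2-like scale, with 1 floor of 3.73 for a count of 0, so it was used only as an alternative. The count table has 47480 gene names, of which 27 read as dates, as spreadsheet programs turn some symbols into, with 2 such names present 2 times. It holds 0 genes of the mitochondrial genome, so the list of these genes was not tested. All columns were matched to a sample by name.

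Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr over the 4 groups (minimum count 10, minimum total 15), which left 16426 genes. Library sizes were scaled by the trimmed mean of M-values (TMM). A quasi-likelihood model with a mean per group was fitted to all 9 libraries (5 residual and 4.58 prior degrees of freedom), so that groups of 2 and 3 share an estimate of the spread, and 5 two-sided comparisons were made from it, including the interaction of population and fraction. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 over all genes in each comparison. CPM are counts scaled to the same effective library size with the TMM factors. Exact permutation tests of 2 against 2 or 3 against 2 libraries cannot go below p = 0.33 or 0.2, so none are given for single values. Total counts were similar in all libraries, and the spread between libraries, with a median biological coefficient of variation of 0.63, set the precision. Genes with a count ranged from 17199 in LSK polysomal 2 to 26046 in MP total 2. They averaged 23400 in LSK total and 18100 in LSK polysomal RNA, and 23100 and 19100 in MP. Whether this bears on the comparisons of polysomal with total RNA was not tested.

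Of 30 gene lists fixed before the data were examined, 29 had at least 5 tested members. They were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, two-sided, with adjustment over all 145 tests. Camera with an estimated correlation was run beside it and called 2 of the 69 lists called with the preset one, the stem cell lists in total and polysomal RNA. Limma's fry, which tests whether a list moves on balance, called 16. P-values given with an estimated correlation or by fry are adjusted over the same 145 tests, also where they are written as p alone. Counts of members are given over all genes and adjusted over the list alone. Lists of stem cells, lymphoid-primed, erythroid, megakaryocyte, and granulocyte and monocyte progenitors and of B cells, T and NK cells, neutrophils, macrophages, and stroma cover the cell types that a marrow sort can hold. Medians and tests differed in sign for some lists, none of them called.

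The rule for named genes was fixed before the data were examined. It takes, in each comparison, the 10 largest increases and 10 largest decreases among genes that passed, had a mean of at least 10 CPM in the higher group and did not overlap between the groups' libraries, leaving out predicted models and clones, or the 5 smallest p-values where none passed. It adds up to 4 members of each list with the smallest p, and Ly6a, Kit, Cd34, Flt3, Malat1, Actb, Gapdh, Cdk1, Mtor, Rptor and Eif4ebp1 in every comparison. Part of the genes it takes are named. Genome positions are those of GRCm38 in the GENCODE M21 annotation, matched by gene symbol.

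The procedure was tested on simulated counts with the spread of the real ones, in which 50 genes were changed by each of 4 fold sizes. Genes changed 16-fold were recovered in 16% of cases for total RNA between populations, 44% for polysomal RNA between populations, 2% for polysomal over total RNA in LSK, 64% in MP and 0% for the interaction, and genes changed 4-fold in 0% to 2%. Each comparison rests on a single random draw, with the same starting mean in all groups. Differences between these percentages for comparisons with the same numbers of libraries thus reflect the draw. A set of 60 genes, all raised 2-fold, was found by camera in every comparison, with p from 4.5e-14 to 2.6e-05. That shift is larger than the median of many lists called below. The simulated genes were drawn independently of each other. The set result therefore does not show how camera performs where the genes of a list vary together, as they may in the real libraries.

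Alternatives planned before the data were examined were DESeq2's size factors, library totals, no filter, a stricter filter (at least 50 counts in every library of a group), DESeq2 1.42.0 with its Wald test, limma voom, a fit of the compared groups alone, the library number as a block, the 10 most abundant genes removed, and each library left out. Removing genes of the mitochondrial genome was planned too and had nothing to remove, and a planned fit on the logarithm of the normalized table was not run, since that table is already on a log2-like scale. Alternatives chosen after seeing the data were 1 surrogate variable (sva 3.50.0), removal of a smooth trend of each library with GC content (known for 96.5% of tested genes), limma on the transformed values, the MP libraries numbered 1 left out, the LSK libraries numbered 2 left out, and the correlation of changes under each setting.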

Results

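RNA was sequenced from 2 populations of mouse hematopoietic cells, each sampled as total RNA and as RNA from the polysomal part of a sucrose gradient. LSK cells are bone marrow cells sorted as lineage-negative and positive for Sca-1 and Kit, and the labels call them stem cells. MP cells are labelled as progenitor cells, with the abbreviation not spelled out in the sources used here. Polysomal RNA is the RNA that sediments with several ribosomes, so its comparison with total RNA bears on the translatome, which the series names as its subject. There were 2 libraries of LSK total RNA, 2 of LSK polysomal RNA, 2 of MP total RNA and 3 of MP polysomal RNA. Total counts per library ranged from 27342343 to 34807735. They averaged 29600000 ± 915000 in LSK total RNA (SD, n = 2) and 28100000 ± 1030000 in LSK polysomal RNA (n = 2). In MP they averaged 30900000 ± 687000 in total RNA (n = 2) and 33900000 ± 1170000 in polysomal RNA (n = 3). Levels below are TMM-normalised CPM, as mean ± SD over the libraries of a group. Changes are log2 fold changes with their standard error (SE). Any p given below with an estimated correlation is an adjusted p.

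The libraries of a group did not resemble each other much more than libraries of different groups. Pearson correlations of log2 CPM were 0.885 to 0.975 between libraries of the same group and reached 0.969 between groups. The median biological coefficient of variation over the tested genes was 0.63. Transcripts of other blood cells differed between libraries of the same group. Immunoglobulin genes took 0.766% and 0.503% of the counts in LSK total 2 and LSK polysomal 2, 0.0914% and 0.108% in LSK total 1 and LSK polysomal 1, and 0.0146% to 0.031% in the MP libraries. A list of 24 genes of maturing neutrophils took 1.51% in MP total 1 and 1.89% in MP polysomal 1, against 0.0585% to 0.115% in the other MP libraries and 0.0699% to 0.306% in the LSK libraries. The labels do not say whether libraries came from separate animals or sorts, so the p-values measure only the spread between these libraries, which may be technical. By the protocol, total RNA was set aside from the lysate ahead of the gradient, so total and polysomal libraries likely share lysates. The labels do not say which libraries share one, so the 2 fractions were compared without pairing.

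**Figure D1:**
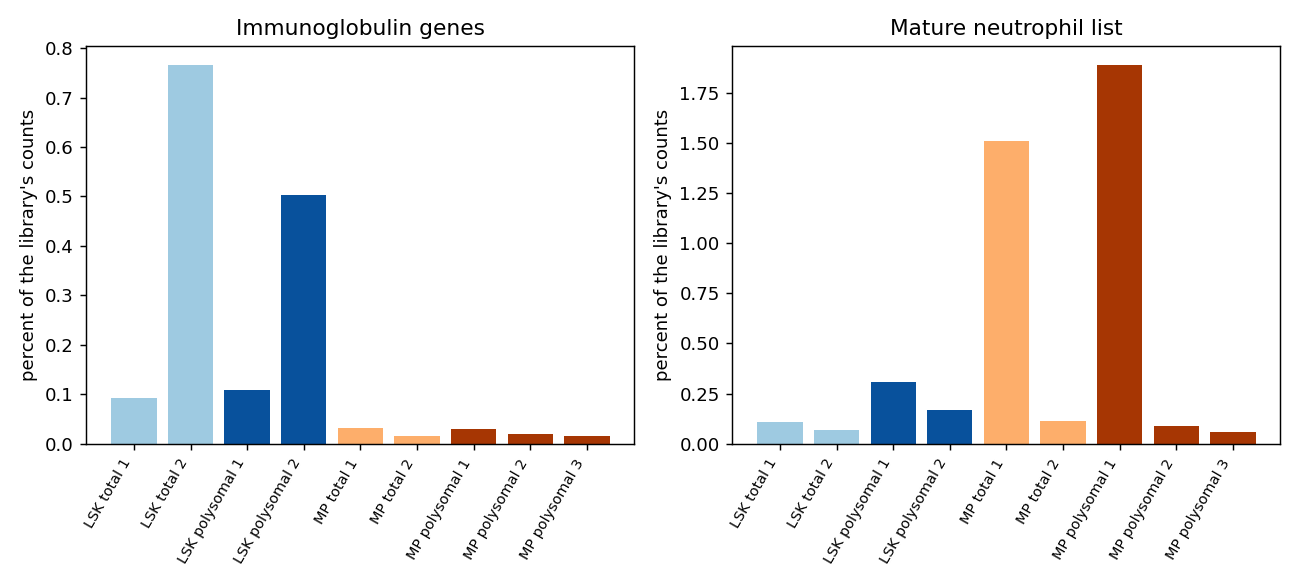
Percent of each library's counts that fell in immunoglobulin genes (left) and in the list of genes of maturing neutrophils (right), with 1 bar for each of the 9 libraries. Immunoglobulin genes reached 0.766% in LSK total 2, and the neutrophil genes reached 1.89% in MP polysomal 1.

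The first comparison asked how the transcriptomes of the populations differ, MP over LSK in total RNA. The list of genes known from hematopoietic stem cells was lower in MP cells, and those of red cell and granulocyte progenitors were higher by camera with a preset correlation. With an estimated correlation the stem cell list passed (adjusted p = 0.027) and the erythroid and granulocyte lists did not (adjusted p = 0.096 and 0.28), and 9 of 38 erythroid and 4 of 32 granulocyte genes passed on their own. Procr, which encodes the endothelial protein C receptor used to mark stem cells, averaged 43.6 ± 12.6 CPM in LSK and 0.626 ± 0.104 CPM in MP (n = 2 each), a log2 change of −6.12 (SE 0.76, adjusted p = 0.0326). The transcription factor gene Hlf averaged 174 ± 3.52 and 8.48 ± 1.71 CPM (log2 change −4.36, SE 0.543, adjusted p = 0.0326). Ermap, an erythroid membrane protein gene, averaged 24.1 ± 7.84 CPM in LSK and 425 ± 79.3 CPM in MP (log2 change 4.14, SE 0.55, adjusted p = 0.0326). Elane, which encodes neutrophil elastase, averaged 1052 ± 52.4 and 9325 ± 2480 CPM (log2 change 3.15, SE 0.457, adjusted p = 0.0326). Procr lies on chromosome 2 (155751117 to 155755471, plus strand), Hlf on chromosome 11 (90336536 to 90390895, minus strand), Ermap on chromosome 4 (119175457 to 119190011, minus strand) and Elane on chromosome 10 (79886247 to 79888215, plus strand) of GRCm38, all as protein-coding genes.

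By edgeR's quasi-likelihood test, 45 of 16426 genes were higher and 134 lower in MP total RNA at an adjusted p under 0.05. An unadjusted p under 0.05 was found for 2804 genes, where 821 are expected by chance. With 1 surrogate variable in the model, added after the data were seen, 1463 genes passed. Scaled by library totals alone, 43 genes were higher and 285 lower, so that the higher share went from 25.1% to 13.1%. The count fell to 0 when LSK total 1, LSK total 2, MP total 1, MP total 2 or any of the MP polysomal libraries was left out, to 0 without both MP libraries numbered 1, and to 0 when only the compared groups were fitted. It was 400 without LSK polysomal 1 and 446 without LSK polysomal 2. Without both LSK libraries numbered 2 it was 211, with 10.9% higher. Ly6a encodes Sca-1, on which LSK cells are sorted, and so serves to check the labels. It averaged 63.8 ± 19.3 CPM in LSK and 0.775 ± 0.27 CPM in MP. Kit, on whose product LSK cells are also sorted, and Cd34 and Flt3 did not pass in total RNA. The sources used here do not say whether Cd34 or Flt3 served to sort either population. Their log2 changes were −0.58 (SE 0.72, adjusted p = 0.75), −1.47 (SE 0.607, adjusted p = 0.255) and −2.80 (SE 0.817, adjusted p = 0.123). The sign for Kit turned to 0.83 without LSK total 1.

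Of 40 stem cell genes, 12 were lower in MP total RNA over all genes tested and 30 adjusted over the list alone. The list had a median log2 change of −3.10 (camera, adjusted p = 5.8e-23) and all 40 members had a negative change. It also passed with an estimated correlation between genes (adjusted p = 0.027). Besides Procr and Hlf, the members with the smallest p were Mecom, a stem cell transcription factor gene, at −5.61 (SE 0.8, adjusted p = 0.0326), and Robo4, a guidance receptor gene, at −5.24 (SE 0.793, adjusted p = 0.0326). Of 25 lymphoid-primed progenitor genes, 4 were lower over all genes and 15 adjusted over the list alone, with a median of −2.32 (adjusted p = 4.3e-07, or adjusted p = 0.21 with an estimated correlation). Dntt, the template-independent DNA polymerase of lymphoid precursors, went from 217 ± 158 to 12.6 ± 5.09 CPM (log2 change −4.11, adjusted p = 0.0365). Gimap6 went from 190 ± 43.3 to 14.9 ± 2.53 CPM (log2 change −3.67, adjusted p = 0.0326). Wfdc17 and Ccr7, a chemokine receptor gene, changed by −4.14 and −4.47.

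Of 38 tested erythroid genes, 9 were higher in MP total RNA over all genes and 16 adjusted over the list alone, with a median of 1.73 (adjusted p = 3.3e-20, or adjusted p = 0.096 with an estimated correlation). Sptb, the red cell beta spectrin gene, changed by 5.74 (SE 0.981, adjusted p = 0.0365), Cldn13 by 4.96 (SE 0.698, adjusted p = 0.0326) and Rhd, a blood group antigen gene, by 4.14 (SE 0.584, adjusted p = 0.0326). The 10 largest increases ranged from 4.32 to 5.74, and besides erythroid list members they held Add2, which encodes a component of the red cell membrane skeleton, at 4.72, and Spon2 at 4.74. Of 32 granulocyte and monocyte progenitor genes, 4 were higher over all genes and 22 adjusted over the list alone, with a median of 2.18 (adjusted p = 1.5e-18, or adjusted p = 0.28 with an estimated correlation). Cebpe, a transcription factor gene of granulocyte maturation, changed by 3.45 (SE 0.59, adjusted p = 0.0365), Ly6c2 by 3.21 and Ms4a3 by 2.86. The list of maturing neutrophil genes had a median of 2.30 (adjusted p = 0.0046, or adjusted p = 0.72 with an estimated correlation), with 0 of 21 tested members passing over all genes and 1 adjusted over the list alone. Its test turned to the opposite sign without MP total 1 (adjusted p = 0.96), the library with 1.51% of counts in this list, and was lost without LSK total 2 (adjusted p = 0.08). Without both MP libraries numbered 1 its sign turned too (adjusted p = 0.85), and it was lost without both LSK libraries numbered 2 (adjusted p = 0.15).

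Genes linked to interferon were lower in MP total RNA, with 2 of 41 lower over all genes, 19 adjusted over the list alone and a median of −1.58 (adjusted p = 1.4e-08, or adjusted p = 0.56 with an estimated correlation). Iigp1, an interferon-inducible GTPase gene, went from 34.0 ± 16.3 to 0.247 ± 0.0742 CPM (log2 change −7.08, SE 1.08, adjusted p = 0.0326). The other member that passed was Ly6a, the sort gene. Of 17 tested B cell markers, 1 was lower over all genes and 3 adjusted over the list alone (median −2.03, adjusted p = 1.5e-05, or adjusted p = 0.36 with an estimated correlation). That gene was Igkc, the kappa light chain constant region (chromosome 6, 70726435 to 70726966, plus strand), at 136 CPM in LSK total 1, 2245 CPM in LSK total 2 and 2.28 ± 0.679 CPM in MP total RNA. Of the 134 lower genes, 5 were immunoglobulin genes. Outside these lists, Bdh2 changed by −6.84 (SE 0.969, adjusted p = 0.0326) and Tnip3 by −6.15 (SE 0.987, adjusted p = 0.0326). Of 20 macrophage and dendritic cell genes 2 were higher, Slc40a1, the iron exporter gene, at 3.28 (SE 0.5, adjusted p = 0.0326) and Vcam1, an adhesion molecule gene, at 4.30 (SE 0.822, adjusted p = 0.0465). That list as a whole did not pass (median −0.81, adjusted p = 0.96).

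Several lists of housekeeping machinery were called higher in MP total RNA with no single member passing over all genes. Median log2 changes were 0.44 for 83 ribosomal protein genes (80 positive, adjusted p = 0.00027, or adjusted p = 0.78 with an estimated correlation), 0.80 for 78 nuclear genes of the respiratory chain (77 positive, adjusted p = 1.5e-08, or 0.56 as the adjusted p with an estimated correlation) and 0.68 for 76 mitochondrial ribosome genes (adjusted p = 6.5e-06, likewise 0.56). They were 0.68 for 36 proteasome genes (adjusted p = 0.00058, or adjusted p = 0.56 with an estimated correlation), 0.56 for 46 S phase genes (adjusted p = 0.0014, likewise 0.44) and 0.53 for 39 initiation factors (adjusted p = 0.018, likewise 0.52). Ribosome assembly factors had a median of 0.48 (adjusted p = 0.0046, with an estimated correlation p = 0.68), lost without LSK total 2 (adjusted p = 0.19). Glycolysis had a median of 0.86 (adjusted p = 0.0089, with an estimated correlation p = 0.70), lost without LSK total 2 (adjusted p = 0.28), without MP total 1 (adjusted p = 0.23) and with the GC trend of each library removed (adjusted p = 0.16). Replication-dependent histones had a median of 0.50 (adjusted p = 0.0029, with an estimated correlation p = 0.77), lost without LSK total 1 (adjusted p = 0.84) and with 1 surrogate variable (adjusted p = 0.13). Genes of the integrated stress response had a median of 0.50 (adjusted p = 0.021, with an estimated correlation p = 0.44), lost without MP total 1 (adjusted p = 0.054) and with 1 surrogate variable (adjusted p = 0.051). Without both LSK libraries numbered 2, ribosome assembly (adjusted p = 0.20) and glycolysis (0.16) were lost. Without both MP libraries numbered 1, glycolysis (adjusted p = 0.20) and the stress response list (0.05) were lost. With the GC trend removed, the medians were 0.225 for ribosomal proteins (adjusted p = 0.015), 0.524 for glycolysis and 0.315 for the stress response list (adjusted p = 0.02). One member of that list passed on its own, Asns, which encodes asparagine synthetase, at 2.72 (SE 0.452, adjusted p = 0.0337). The control genes Actb and Gapdh changed by 0.77 (SE 0.585, adjusted p = 0.563) and 0.58 (SE 0.468, adjusted p = 0.592).

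The second comparison set MP over LSK in polysomal RNA. By camera with a preset correlation, the stem cell, lymphoid and interferon lists were lower in the polysomal RNA of MP cells and the erythroid and granulocyte lists higher. With an estimated correlation only the stem cell list of these 5 passed (adjusted p = 0.027), against 0.12, 0.43, 0.12 and 0.43 for the others in this order. Procr averaged 57.5 ± 27.8 CPM in LSK (n = 2) and 0.675 ± 0.227 CPM in MP (n = 3), a log2 change of −6.41 (SE 0.643, adjusted p = 0.00696). Esam, an endothelial and stem cell adhesion molecule gene, averaged 170 ± 11.1 and 5.80 ± 2.08 CPM (log2 change −4.87, SE 0.545, adjusted p = 0.00696). Flt3, a cytokine receptor gene of lymphoid-primed progenitors, changed by −4.89 (SE 0.758, adjusted p = 0.015). Car1, the red cell carbonic anhydrase gene, averaged 484 ± 82.4 CPM in LSK and 4575 ± 932 CPM in MP (log2 change 3.24, SE 0.465, adjusted p = 0.012), and Elane averaged 1041 ± 25.3 and 6107 ± 1760 CPM (log2 change 2.55, SE 0.426, adjusted p = 0.0182).

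By edgeR's quasi-likelihood test, 86 genes were higher and 465 lower in MP polysomal RNA, and 2924 had an unadjusted p under 0.05. With 1 surrogate variable, added after the data were seen, 1825 genes passed. The count fell to 0 without MP polysomal 1 or MP polysomal 2 and without both MP libraries numbered 1, to 25 without MP polysomal 3, to 203 without LSK polysomal 2 and to 197 without both LSK libraries numbered 2. The higher share went from 15.6% to 2.96% without LSK polysomal 2 (6 higher genes), 5.08% without both LSK libraries numbered 2 (10), 8% without MP polysomal 3 (2) and 28.1% without LSK polysomal 1 (145 of 516). It was 304 when only the compared groups were fitted. Of the genes called in total RNA, 36 were also higher here where 0.24 would be shared by independent lists, and 118 were also lower, where 3.8 would be. No gene was called in opposite directions. Across all 16426 genes the changes in total and in polysomal RNA had a Pearson correlation of 0.588 and a Spearman correlation of 0.428, which describe genes and not replicates. Over the 9073 genes with a mean of at least 10 CPM these were 0.519 and 0.283, with 56.2% of genes changed in the same direction. Pearson's r was 0.314 without LSK polysomal 1, 0.351 without LSK total 2 and 0.314 with no filter on low counts.

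Of 40 stem cell genes, 16 were lower in polysomal RNA over all genes and 33 adjusted over the list alone, with a median of −2.73 (adjusted p = 2.1e-27, and adjusted p = 0.027 with an estimated correlation). Hlf changed by −4.05 (SE 0.454, adjusted p = 0.00696) and Robo4 by −6.11 (SE 0.688, adjusted p = 0.00696). Of 25 lymphoid-primed genes, 7 were lower over all genes and 14 adjusted over the list alone (median −2.0, adjusted p = 5.1e-11, or adjusted p = 0.12 with an estimated correlation). Dntt averaged 603 ± 136 CPM in LSK and 16.1 ± 4.61 CPM in MP, and Gimap6 392 ± 13.5 and 19.7 ± 5.78 CPM. Interferon genes were lower for 14 of 41 members over all genes and 24 adjusted over the list alone (median −1.82, adjusted p = 1.7e-14, or adjusted p = 0.43 with an estimated correlation). Rtp4 changed by −3.99 (SE 0.655, adjusted p = 0.0175), Oasl2 by −3.46 (SE 0.617, adjusted p = 0.0211) and Usp18 by −2.67 (SE 0.473, adjusted p = 0.0208). Each of these calls was lost without MP polysomal 1 or MP polysomal 2, as were all 85 results of passing genes that were followed across settings. None of the 85 changed sign under any setting, which was unlikely from the start for genes picked because they passed in these data.

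Erythroid genes were higher for 11 of 38 members over all genes and 17 adjusted over the list alone (median 1.42, adjusted p = 1.3e-12, or adjusted p = 0.12 with an estimated correlation). Ermap changed by 4.08 (SE 0.534, adjusted p = 0.00941) and Ank1, the red cell ankyrin gene, by 3.79 (SE 0.632, adjusted p = 0.0181). Granulocyte and monocyte progenitor genes were higher for 4 of 32 members over all genes and 21 adjusted over the list alone (median 1.89, adjusted p = 2.4e-12, or adjusted p = 0.43 with an estimated correlation), among them Cebpe at 3.16 (SE 0.562, adjusted p = 0.0211), Ly6c2 at 2.91 and Ms4a3 at 2.6. MP polysomal 1 held 1.89% of its counts in genes of maturing neutrophils, and that list did not pass in polysomal RNA (median 1.40, adjusted p = 0.63). Macrophage and dendritic cell genes went both ways, with 1 of 20 higher and 6 lower over all genes, and 2 higher and 10 lower adjusted over the list alone (median −1.82, adjusted p = 0.0041, or adjusted p = 0.62 with an estimated correlation, lost without MP polysomal 3 at an adjusted p of 0.056). The higher gene was Slc40a1 at 3.06 (SE 0.477, adjusted p = 0.015). H2-Aa and H2-Eb1, which encode chains of antigen-presenting MHC class II molecules, were lower at −2.22 (SE 0.447, adjusted p = 0.0318) and −2.65 (SE 0.536, adjusted p = 0.0319).

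B cell markers were lower for 4 of 17 members over all genes and 9 adjusted over the list alone (median −2.15, adjusted p = 9.3e-09, or adjusted p = 0.12 with an estimated correlation). Among the 465 lower genes, 22 were immunoglobulin genes. Igha, the constant region of the IgA heavy chain (chromosome 12, 113254830 to 113260236, minus strand), was at 50.9 CPM in LSK polysomal 1, 1088 CPM in LSK polysomal 2 and 0.554 ± 0.464 CPM in MP polysomal RNA. Jchain, which joins secreted antibody units, averaged 57.6 ± 41 CPM in LSK and 0.320 ± 0.0784 CPM in MP (adjusted p = 0.0341). Cd79a, part of the B cell receptor, averaged 6.32 ± 4.05 and 0.568 ± 0.315 CPM (adjusted p = 0.0325). The largest fitted decreases belonged to immunoglobulin genes close to or at 0 counts in MP cells, and no fold change is given for these. T and NK cell markers were lower for 2 of 13 members over all genes and 3 adjusted over the list alone (median −1.64, adjusted p = 0.0076, or adjusted p = 0.48 with an estimated correlation, lost without LSK polysomal 1 at an adjusted p of 0.076). The 2 genes were Lck at −4.67 (SE 0.627, adjusted p = 0.0101) and Cd247 at −3.31 (SE 0.584, adjusted p = 0.0206), both of T cell receptor signalling.

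Genes linked to quiescence and hypoxia were lower for 4 of 27 members over all genes and 4 adjusted over the list alone (median −0.73, adjusted p = 0.022, or adjusted p = 0.43 with an estimated correlation, lost without MP polysomal 2 at an adjusted p of 0.065). Txnip, an inhibitor of thioredoxin, averaged 2049 ± 346 CPM in LSK and 501 ± 19.2 CPM in MP (log2 change −2.03, SE 0.388, adjusted p = 0.0273). Ndrg1, a stress response gene, changed by −2.73 (SE 0.568, adjusted p = 0.0347). Aldoc, a glycolytic aldolase gene, went from 44.9 ± 6.33 to 1.51 ± 0.176 CPM (log2 change −4.89, SE 0.512, adjusted p = 0.00696), while the glycolysis list did not pass (median −0.37, adjusted p = 0.11). Of the integrated stress response genes, Asns was higher at 1.91 (SE 0.416, adjusted p = 0.0408) and Trib3 lower at −3.67 (SE 0.743, adjusted p = 0.0321), with a list median of 0.40 (adjusted p = 0.10). Ribosome assembly factors had a median of 0.85 (adjusted p = 2.8e-05, with an estimated correlation p = 0.56) and initiation factors of 0.58 (adjusted p = 0.0051, with an estimated correlation p = 0.44), with 0 members passing over all genes. G2 and M phase genes had a median of 0.56 (adjusted p = 0.0044, with an estimated correlation p = 0.70), lost without LSK polysomal 2 (adjusted p = 0.19) and without both LSK libraries numbered 2 (adjusted p = 0.17). Histones had a median of 0.63 (adjusted p = 0.013, with an estimated correlation p = 0.82), lost without LSK polysomal 1 (adjusted p = 0.82) and without MP polysomal 3 (adjusted p = 0.38), with a median of 1.19 once the GC trend was removed (adjusted p = 0.00063). Nuclear noncoding RNAs had a median of 1.07 (adjusted p = 0.043, with an estimated correlation p = 0.56), lost without LSK polysomal 2 (adjusted p = 0.34), MP polysomal 1 (adjusted p = 0.071) or MP polysomal 3 (adjusted p = 0.054) and with the GC trend removed (adjusted p = 0.07). They were also lost without both LSK libraries numbered 2 (adjusted p = 0.35) and without both MP libraries numbered 1 (adjusted p = 0.065).

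**Figure D2:**
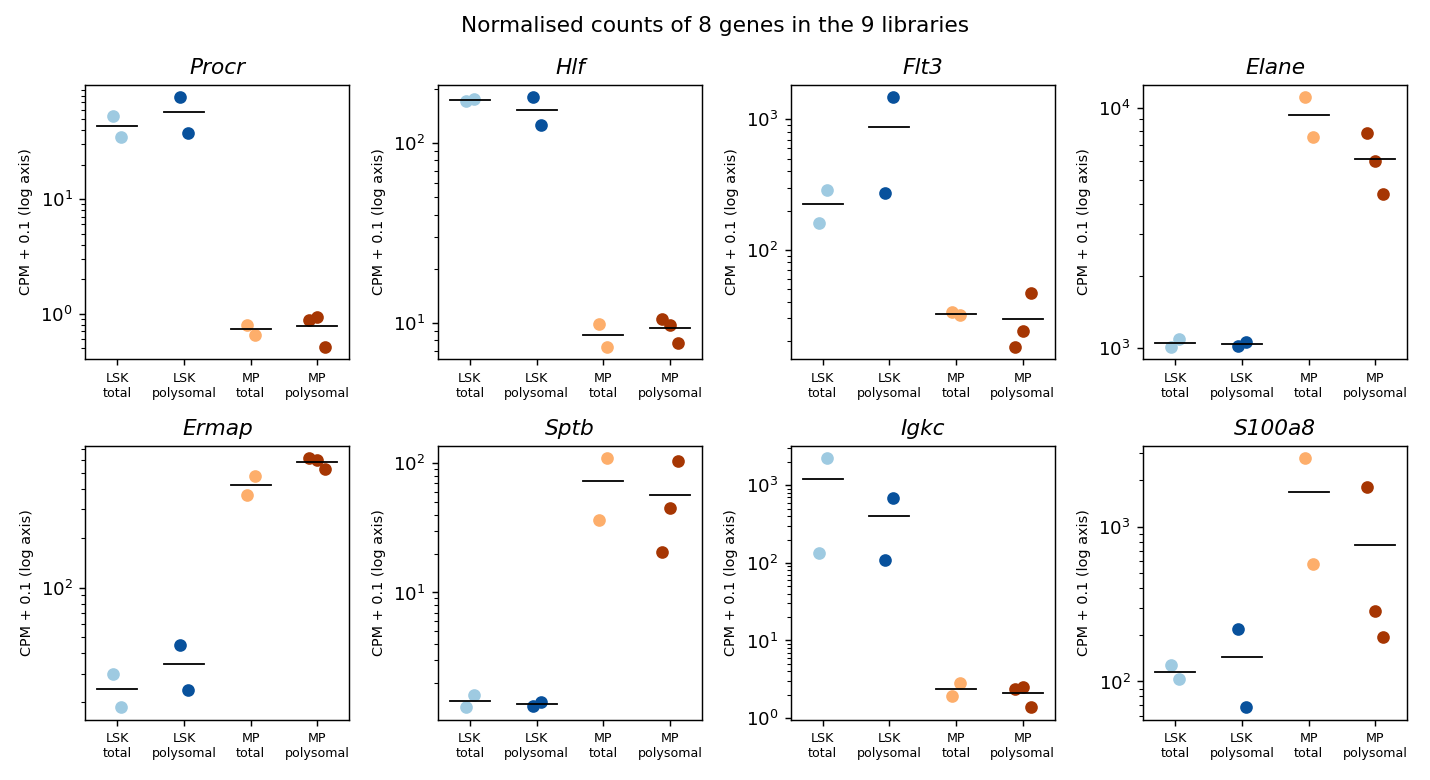
Normalised counts of 8 genes in the 9 libraries, as CPM plus 0.1 on log axes, with 1 point per library and a line at the group mean. Procr and Hlf were lower and Elane, Ermap and Sptb higher in MP libraries. Flt3 was lower too, but passed only in polysomal RNA. Igkc reached 2245 CPM in LSK total 2, and S100a8, a neutrophil gene, spread widely between MP libraries.

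The third comparison set polysomal over total RNA in LSK cells. No single gene passed, and the differences showed as shifts of whole lists. The lists of nuclear noncoding RNAs and snoRNA host genes had lower levels in polysomal RNA by camera with a preset correlation, and that of glycolysis higher levels. These calls were lost with an estimated correlation (adjusted p = 0.21, 0.21 and 0.47). Malat1, a nuclear noncoding RNA (chromosome 19, 5795690 to 5802672, minus strand), averaged 829 ± 211 CPM in total RNA and 98.5 ± 120 CPM in polysomal RNA (n = 2 each, log2 change −3.07, SE 0.976, adjusted p = 0.256). Gas5, which hosts small nucleolar RNAs, averaged 495 ± 0.424 and 155 ± 45.8 CPM (log2 change −1.68, SE 0.459, adjusted p = 0.224). Tpi1, a glycolytic enzyme gene, averaged 481 ± 208 and 1751 ± 452 CPM (log2 change 1.86, SE 0.491, adjusted p = 0.217).

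By edgeR's quasi-likelihood test 0 genes passed, with 1981 at an unadjusted p under 0.05 and a smallest adjusted p of 0.21. DESeq2's Wald test called 37 genes higher and 396 lower, limma voom called 0, limma on the authors' transformed values called 486, and edgeR called 547 with no filter on low counts and 7 with 1 surrogate variable. In simulated data with this spread, genes changed 16-fold were recovered in 2% of cases in this comparison, so a count of 0 does not show that genes were alike. The 5 genes with the smallest p, none passing, included Mdm2, which encodes the ubiquitin ligase of p53, at −3.52 (SE 0.595, adjusted p = 0.212), Sorl1 at 2.81 (SE 0.515, adjusted p = 0.212) and Prpf39, a splicing factor gene, at −3.59 (SE 0.671, adjusted p = 0.212).

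All 13 nuclear noncoding RNAs had negative changes, with a median of −2.10 (adjusted p = 3.3e-07, or adjusted p = 0.21 with an estimated correlation) and 6 lower adjusted over the list alone. Firre and Kcnq1ot1 had log2 changes of −4.33 (SE 0.922) and −3.85 (SE 0.966). All 18 snoRNA host genes were negative as well, with a median of −1.93 (adjusted p = 4.6e-08, or adjusted p = 0.21 with an estimated correlation) and 9 lower adjusted over the list alone. Of 50 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, 46 were negative (median −1.67, adjusted p = 4.4e-05, or adjusted p = 0.70 with an estimated correlation). With the GC trend of each library removed, the medians were −1.17 for nuclear noncoding RNAs (adjusted p = 1.3e-05) and −1.29 for snoRNA host genes (6.4e-06). The histone test was lost without LSK polysomal 1 (adjusted p = 0.38) and turned to the opposite sign without LSK total 2 (adjusted p = 0.95). Ribosomal protein genes were negative for 70 of 83 (median −0.47, adjusted p = 0.0094, or adjusted p = 0.88 with an estimated correlation). That test was lost without LSK polysomal 2 (adjusted p = 0.60), LSK total 2 (adjusted p = 0.58), MP total 1 (adjusted p = 0.062) or both MP libraries numbered 1 (adjusted p = 0.078), and turned to the opposite sign without both LSK libraries numbered 2 (adjusted p = 0.57).

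All 21 glycolysis genes had positive changes, with a median of 1.45 (adjusted p = 1.6e-09, or adjusted p = 0.47 with an estimated correlation) and 2 higher adjusted over the list alone. Eno1 and Aldoc had log2 changes of 1.86 (SE 0.554) and 2.11 (SE 0.535). Proteasome genes were positive for 32 of 36 (median 0.63, adjusted p = 8.1e-05, with an estimated correlation p = 0.56), among them Psmc5 at 1.76 (SE 0.509). S phase genes were positive for 40 of 46 (median 0.50, adjusted p = 0.00017, with an estimated correlation p = 0.43), among them the replicative helicase gene Mcm7 at 1.84 (SE 0.523). Random lists matched on coding length and expression had medians of 0.504 for the proteasome and 0.459 for S phase. The proteasome lay at percentile 81.8 of these and S phase at 61.8, so coding length and expression are not ruled out for either. Glycolysis lay at percentile 100, cholesterol synthesis at 99.4 and interferon genes at 97.8. Cholesterol synthesis genes were positive for 23 of 25 (median 0.73, adjusted p = 0.00091, with an estimated correlation p = 0.56). Erythroid genes were positive for 32 of 38 (median 0.35, adjusted p = 0.00091, with an estimated correlation p = 0.43). With the GC trend removed, the medians were 0.96 for glycolysis (adjusted p = 4.7e-07), 0.453 for cholesterol synthesis (0.0023) and 0.184 for erythroid genes (0.021). Macrophage and dendritic cell genes had a median of 1.80 (adjusted p = 5.7e-07, with an estimated correlation p = 0.44), with the complement gene C1qa at 3.88 (SE 0.975) and Vcam1 at 2.69 (SE 0.765). Maturing neutrophil genes had a median of 1.50 (adjusted p = 0.0081, with an estimated correlation p = 0.74), lost without LSK polysomal 1 (adjusted p = 0.13), LSK total 2 (adjusted p = 0.12) or both LSK libraries numbered 2 (adjusted p = 0.075), where LSK polysomal 1 held 0.306% of counts in this list and LSK total 2 held 0.0699%. Interferon genes had a median of 0.51 (adjusted p = 0.00031, with an estimated correlation p = 0.68), lost without LSK total 2 (adjusted p = 0.059). Lymphoid-primed genes had a median of 0.42 (adjusted p = 0.036, with an estimated correlation p = 0.56), lost without LSK polysomal 1 (adjusted p = 0.28) or LSK total 2 (adjusted p = 0.061). Messages with a terminal oligopyrimidine start other than those of ribosomal proteins, translation factors among them, had a median of 0.16 (adjusted p = 0.035, or adjusted p = 0.67 with an estimated correlation). This call was lost without LSK polysomal 1 or LSK total 1.

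The fourth comparison set polysomal over total RNA in MP cells. Again no single gene passed. By camera with a preset correlation, the lists of ribosomal protein, respiratory chain and histone genes were lower in polysomal RNA and that of G2 and M phase genes was higher. These 4 calls were lost with an estimated correlation (adjusted p = 0.56 each) and by fry (adjusted p = 0.12, 0.11, 0.34 and 0.37). Rps19, a ribosomal protein gene (chromosome 7, 24884371 to 24889806, plus strand), averaged 594 ± 120 CPM in total RNA (n = 2) and 227 ± 62.9 CPM in polysomal RNA (n = 3), a log2 change of −1.39 (SE 0.415, adjusted p = 0.656). Ndufb9, a complex I subunit gene, averaged 314 ± 66.7 and 122 ± 43.9 CPM (log2 change −1.36, SE 0.488, adjusted p = 0.656). Top2a, the mitotic topoisomerase gene, averaged 160 ± 74.1 and 987 ± 257 CPM (log2 change 2.63, SE 0.839, adjusted p = 0.656).

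By edgeR's quasi-likelihood test 0 genes passed, with 1243 at an unadjusted p under 0.05 and a smallest adjusted p of 0.47. DESeq2's Wald test called 30 genes higher and 0 lower, limma voom and limma on the transformed values called 0, and edgeR called 22 with no filter on low counts and 1 with 1 surrogate variable. The genes with the smallest p, none passing, included Zfp46, a zinc finger gene, at −4.02 (SE 0.59, adjusted p = 0.471), and Sf3b1, which encodes a core part of the spliceosome, at 2.63 (SE 0.596, adjusted p = 0.656).

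Ribosomal protein genes were negative for 80 of 83 (median −0.89, adjusted p = 3.2e-19, or adjusted p = 0.56 with an estimated correlation). Rpl35, Rps28 and Rpl36 had log2 changes of −1.81 (SE 0.518), −1.77 (SE 0.516) and −1.63 (SE 0.482). Respiratory chain genes were negative for 70 of 78 (median −0.67, adjusted p = 7.9e-09, with an estimated correlation p = 0.56), among them the ATP synthase genes Atp5e at −1.42 (SE 0.45) and Usmg5 at −1.33 (SE 0.462). Mitochondrial ribosome genes were negative for 66 of 76 (median −0.41, adjusted p = 0.0016, with an estimated correlation p = 0.68), lost without MP polysomal 3 (adjusted p = 0.063). All 50 histone genes were negative (median −1.61, adjusted p = 2.3e-11, with an estimated correlation p = 0.56), with Hist4h4 at −1.72 (SE 0.559). The snoRNA host genes had a median of −1.59 (adjusted p = 3e-10, or adjusted p = 0.15 with an estimated correlation), 17 of 18 negative and 3 lower adjusted over the list alone, with Snhg6 and Snhg9 at −2.08 (SE 0.61) and −3.42 (SE 0.906). Immediate early and heat shock genes had a median of −1.01 (adjusted p = 0.0077, with an estimated correlation p = 0.56), lost without MP total 1 (adjusted p = 0.19) or both MP libraries numbered 1 (adjusted p = 0.18).

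G2 and M phase genes were positive for 30 of 43 (median 0.98, adjusted p = 7.7e-07, or adjusted p = 0.56 with an estimated correlation), with the mitotic kinesin genes Kif4 and Kif11 at 2.68 (SE 0.799) and 2.20 (SE 0.736). Cdk1, the kinase that drives mitosis, averaged 305 ± 51.1 CPM in total RNA and 349 ± 111 CPM in polysomal RNA. Ribosome assembly factors were positive for 36 of 54 (median 0.52, adjusted p = 0.0016, with an estimated correlation p = 0.63), with Heatr1 at 1.91 (SE 0.725). S phase genes were positive for 33 of 46 (median 0.25, adjusted p = 0.0051, with an estimated correlation p = 0.48). Random lists matched to S phase on coding length and expression had a median of 0.255 in MP. S phase lay at percentile 48.7 of these, so coding length and expression are not ruled out for its shift. G2 and M phase genes lay at percentile 100, ribosome assembly factors at 96.8 and interferon genes at 98.9. Interferon genes had a median of 0.28 (adjusted p = 0.0048, with an estimated correlation p = 0.72), lost without MP polysomal 1 (adjusted p = 0.15) or MP total 2 (adjusted p = 0.41). Macrophage and dendritic cell genes had a median of 0.52 (adjusted p = 0.02, with an estimated correlation p = 0.68), lost without MP polysomal 1 (adjusted p = 0.15) or MP total 2 (adjusted p = 0.49) and with 1 surrogate variable (adjusted p = 0.078). The nuclear noncoding list, called in LSK, was not called here (median −0.47, adjusted p = 0.14).

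**Figure D3:**
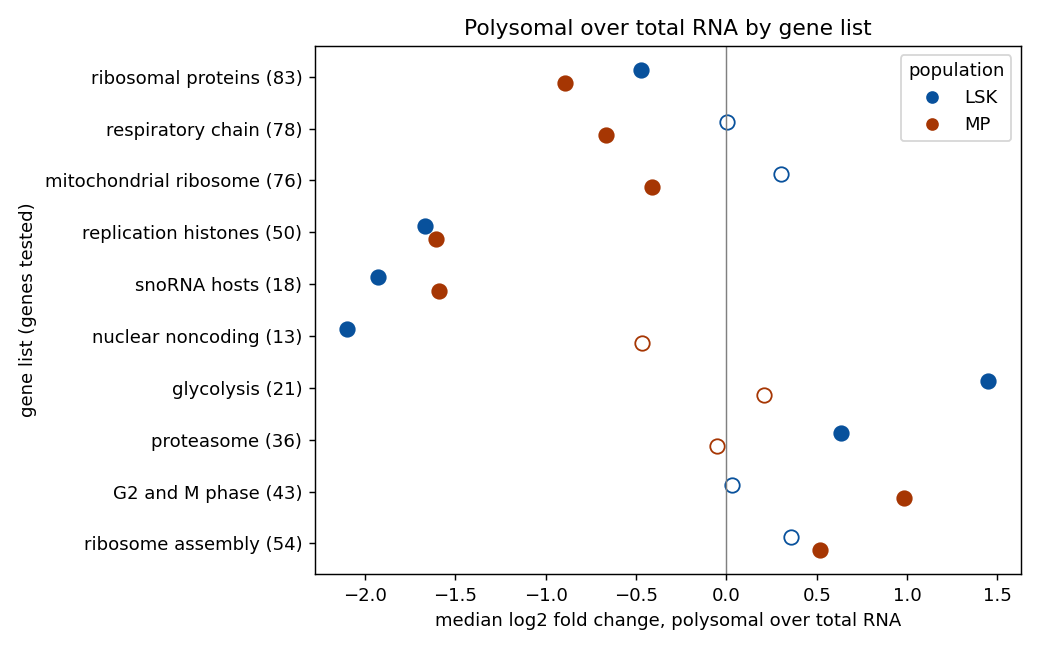
Median log2 fold change of polysomal over total RNA for 10 gene lists in LSK (blue) and MP (red), with the number of tested genes in brackets. Filled points passed the camera test with a preset correlation at an adjusted p of 0.05 and open points did not. Ribosomal proteins were at −0.47 in LSK and −0.89 in MP, and glycolysis at 1.45 and 0.21.

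The fifth comparison asked whether the polysomal over total ratio differs between the populations, as an interaction term, MP over LSK. No single gene passed. By camera with a preset correlation, the ratio was lower in MP for the glycolysis, respiratory chain and proteasome lists and higher for nuclear noncoding RNAs. These calls were lost with an estimated correlation (adjusted p = 0.56, 0.56, 0.56 and 0.43) and by fry (0.28, 0.21, 0.19 and 0.12). All 21 glycolysis genes had a lower ratio in MP (median −1.22, adjusted p = 5.3e-07, or adjusted p = 0.56 with an estimated correlation), with Tpi1 at −1.46 (SE 0.643) and Eno1 at −1.46 (SE 0.725). The glycolysis call was lost without both LSK libraries numbered 2 (adjusted p = 0.052), and its median was −0.475 with the GC trend of each library removed (adjusted p = 0.00024). Nuclear noncoding RNAs had a higher ratio in MP for 12 of 13 (median 2.08, adjusted p = 0.00027, or adjusted p = 0.43 with an estimated correlation), with Malat1 at 4.12 (SE 1.29, adjusted p = 0.877), Firre at 2.96 (SE 1.13) and Tug1 at 2.81 (SE 1.08). Their median was 1.29 with the GC trend removed (adjusted p = 0.0047). This difference came in part from total RNA. The summed CPM of the list averaged 1334 ± 71.5 in LSK total and 310.8 ± 27.7 in MP total RNA. It averaged 272.4 ± 231 in LSK polysomal and 485.2 ± 102 in MP polysomal RNA. MP over LSK, the list median was −1.03 in total RNA (camera, adjusted p = 0.11) and 1.07 in polysomal RNA. The higher ratio alone thus does not show more of these RNAs on polysomes in MP.

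By edgeR's quasi-likelihood test 0 genes passed, with 869 at an unadjusted p under 0.05 where 821 are expected by chance. DESeq2's Wald test called 1 gene, limma voom and limma on the transformed values 0, and edgeR 4 with no filter and 0 with 1 surrogate variable. Genes changed 16-fold were recovered in 0% of cases in simulated data for this term. The genes with the smallest p, none passing, included Prpf39 at 4.28 (SE 0.872, adjusted p = 0.877), Lysmd3 at 3.64 (SE 0.842) and Ncapg, a condensin gene, at 3.64 (SE 0.88). Across all tested genes the polysomal over total changes in LSK and MP had a Pearson correlation of 0.39 and a Spearman correlation of 0.28, and over the 9073 genes with a mean of at least 10 CPM these were 0.084 and 0.0611.

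Of the 29 lists, 13 were called for this term and 0 with an estimated correlation. Respiratory chain genes had a lower ratio in MP for 76 of 78 (median −0.72, adjusted p = 2e-07, with an estimated correlation p = 0.56), with the complex I gene Ndufa9 at −1.50 (SE 0.681). Mitochondrial ribosome genes had a lower ratio for 71 of 76 (median −0.71, adjusted p = 2.2e-05, with an estimated correlation p = 0.58). Proteasome genes had a lower ratio for 28 of 36 (median −0.71, adjusted p = 0.00091, or adjusted p = 0.56 with an estimated correlation), lost with the library number as a block (adjusted p = 0.076). Ribosomal protein genes had a lower ratio for 80 of 83 (median −0.47, adjusted p = 0.00025, with an estimated correlation p = 0.78), lost without LSK polysomal 1 (adjusted p = 0.24) or MP polysomal 3 (adjusted p = 0.11). Messages with a terminal oligopyrimidine start other than those of ribosomal proteins, translation factors among them, had a median of −0.56 (adjusted p = 0.043, or adjusted p = 0.68 with an estimated correlation). This call was lost without LSK polysomal 1, LSK total 1, MP polysomal 3 (adjusted p = 0.25) or MP total 2. With the library number as a block, it was lost (adjusted p = 0.30), as was the ribosomal protein call (0.17). With the GC trend removed, the medians were −0.414 for the respiratory chain (adjusted p = 8.2e-07), −0.332 for the mitochondrial ribosome (2.6e-06), −0.45 for the proteasome (6.5e-05), −0.0956 for ribosomal proteins (0.024) and −0.358 for the other oligopyrimidine messages (0.015). G2 and M phase genes had a median of 0.45 (adjusted p = 0.0048, with an estimated correlation p = 0.70), lost without LSK total 1 (adjusted p = 0.60) or MP total 2 (adjusted p = 0.24). Genes of the mTOR pathway, which controls translation, were not called (median −0.44, adjusted p = 0.14, 37 genes), and Mtor, Rptor and Eif4ebp1 were at −0.08 (SE 0.768), −0.02 (SE 0.773) and −2.21 (SE 1.73), with signs that turned under other settings. Leaving out LSK polysomal 1 gave 0.50 for Mtor, leaving out LSK total 2 gave 0.30 for Rptor, and leaving out LSK polysomal 2 gave 1.26 for Eif4ebp1. Cdk1 was at −0.48 (SE 0.638, adjusted p = 0.902).

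Lists of other cell types also differed in this ratio, each with a lower ratio in MP. The medians were −1.34 for maturing neutrophils (adjusted p = 0.0077, with an estimated correlation p = 0.74), −1.05 for macrophages and dendritic cells (adjusted p = 0.0023, with an estimated correlation p = 0.58), −1.12 for stroma and endothelium (adjusted p = 0.039, with an estimated correlation p = 0.43), −0.56 for erythroid genes (adjusted p = 0.019, with an estimated correlation p = 0.56) and −0.50 for granulocyte and monocyte progenitors (adjusted p = 0.045, with an estimated correlation p = 0.72). The neutrophil test turned to the opposite sign without MP total 1 (adjusted p = 0.48), which held 1.51% of its counts in that list, and was lost without LSK polysomal 1 (0.20), LSK total 2 (0.15), MP polysomal 2 (0.057) or MP polysomal 3 (0.20), given as adjusted p. The macrophage test was lost without LSK total 2 (adjusted p = 0.16), MP polysomal 3 (0.063) or MP total 1 (0.14). The stromal test was lost without LSK polysomal 1 (adjusted p = 0.098), LSK total 2 (0.23), MP polysomal 3 (0.087) or MP total 2 (0.22) and with the GC trend removed (0.11). The erythroid test was lost without LSK polysomal 1 (adjusted p = 0.081), LSK total 1 (0.17) or MP total 2 (0.17), with 1 surrogate variable (0.10) and with the GC trend removed (0.47). The granulocyte test was lost without LSK polysomal 1 (adjusted p = 0.69), LSK total 2 (0.12), MP polysomal 2 (0.083), MP polysomal 3 (0.26) or MP total 1 (0.62), with DESeq2's size factors (0.052) and with the GC trend removed (0.079). Without both LSK libraries numbered 2, the neutrophil (adjusted p = 0.059), macrophage (0.16) and stromal (0.27) tests were lost, and without both MP libraries numbered 1 the granulocyte test (0.13). With the GC trend removed, the medians were −0.637 for stroma, 0.0188 for erythroid genes and −0.103 for granulocyte progenitors. With the library number as a block, the neutrophil (camera, adjusted p = 0.19), macrophage (0.13), stromal (0.11) and granulocyte (0.38) tests were lost.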

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

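The tests of matched random lists and of the GC trend for ribosomal protein and respiratory chain mRNAs within MP cells were written before their results were seen. Those for other lists, for LSK cells and for the difference between populations, with the refits without each library's GC trend, were chosen after. For 13 lists the polysomal over total ratio differed between LSK and MP by the interaction term (camera, adjusted p under 0.05). The median difference, MP over LSK, was −1.22 for glycolysis (adjusted p = 5.3e-07), −0.722 for the respiratory chain (2e-07), −0.707 for the mitochondrial ribosome (2.2e-05), −0.706 for the proteasome (0.00091), −0.471 for ribosomal proteins (0.00025) and −0.562 for other messages with a terminal oligopyrimidine start (0.043). It was −1.34 for maturing neutrophils (0.0077), −1.05 for macrophages and dendritic cells (0.0023), −1.12 for stroma and endothelium (0.039), −0.557 for erythroid genes (0.019) and −0.496 for granulocyte and monocyte progenitors (0.045). It was 2.08 for nuclear noncoding RNAs (0.00027) and 0.453 for G2 and M phase genes (0.0048). None of the 13 passed camera with an estimated correlation, where the smallest adjusted p among them was 0.43. With the library number as a block, these camera calls were lost: granulocyte progenitors (adjusted p = 0.38), neutrophils (0.19), macrophages (0.13) and stroma (0.11). Ribosomal proteins (0.17), the other oligopyrimidine messages (0.30) and the proteasome (0.076) were lost too.

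The ratio also followed GC content, with a Spearman correlation of −0.57 over 12937 genes for the interaction, 0.39 in LSK and −0.3 in MP. With the GC trend removed, glycolysis was at −0.475 (adjusted p = 0.00024), the respiratory chain at −0.414 (8.2e-07), the mitochondrial ribosome at −0.332 (2.6e-06), the proteasome at −0.45 (6.5e-05), nuclear noncoding RNAs at 1.29 (0.0047) and G2 and M phase genes at 0.614 (0.0048). Ribosomal proteins were at −0.0956 (0.024), the other oligopyrimidine messages at −0.358 (0.015), maturing neutrophils at −1.63 (0.00069) and macrophages at −0.819 (0.0007). Erythroid, stromal and granulocyte lists were at 0.0188, −0.637 and −0.103 and no longer passed (adjusted p = 0.47, 0.11 and 0.079). Against 10000 random lists matched on coding length and expression, the difference between populations lay at percentile 0 for glycolysis and the respiratory chain, 0.29 for the mitochondrial ribosome and 99.9 for G2 and M phase genes. It lay at percentile 5.29 for the proteasome, inside the middle 95% of −0.747 to −0.143, and at percentile 75 for ribosomal proteins. Coding length and expression are thus not ruled out for these 2 lists. The random lists were not matched on GC content, and their genes were drawn independently of each other. Most of the median went with the GC trend for glycolysis (−1.22 to −0.475), the mitochondrial ribosome (−0.707 to −0.332) and ribosomal proteins (−0.471 to −0.0956). GC content is thus not ruled out as a part of these differences.

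Within MP cells, ribosomal protein and respiratory chain mRNAs had low polysomal over total ratios, with medians of −0.893 and −0.668 by camera with a preset correlation, calls that were lost with an estimated one (adjusted p = 0.56 each) and by fry (0.12 and 0.11), and 0 members passed on their own. Short messages hold fewer ribosomes, and the ratio rose with coding length in MP (Spearman 0.39) but hardly in LSK (0.084). Each median lay at percentile 0 of 10000 random lists matched on coding length and expression (middle 95% of −0.393 to −0.166 and −0.451 to −0.167). The medians were −0.821 and −0.705 with the GC trend removed. For the values in these libraries, this argues against coding length or the GC trend as the whole cause. The random genes were drawn independently, so the middle 95% leaves out variation that the genes of a list share. The percentiles thus do not tell a property of these messages from a shared swing of the list between libraries. In LSK, ribosomal proteins lay at percentile 0 as well (median −0.473, middle 95% of 0.0358 to 0.386), and the respiratory chain at percentile 30. The low ratio of ribosomal protein mRNAs was thus not particular to MP. The LSK call for ribosomal proteins was lost with some libraries left out. Reads shared with pseudogenes were not tested, and a difference in translation between messages may be behind the pattern, which stays a hypothesis. A list shift in 5 libraries also does not tell translation from loss of these messages during the gradient, and no biological explanation was tested.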

How the results depend on the processing

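The surrogate variable, GC trend, transformed values and the omission of both MP libraries numbered 1 or both LSK libraries numbered 2 were chosen after seeing the data, and the other settings were planned. Of 85 results of passing genes, 85 kept their direction under every setting that tested them. These genes were picked because they passed in the same data, so a change of sign was unlikely from the start. All 85 still passed with DESeq2's size factors, no filter, DESeq2's Wald test, 1 surrogate variable and the transformed values, 74 with the block, 37 with the compared groups only, 9 without MP polysomal 3 and 0 without MP polysomal 1, MP polysomal 2 or both MP libraries numbered 1.

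In total RNA between populations (179 genes) the count was 328 with library totals, 1206 with no filter, 393 with the strict filter, 1471 with DESeq2's Wald test, 542 with limma voom, 0 with the compared groups only, 1463 with 1 surrogate variable, 376 with the GC trend removed, 850 with the transformed values, 0 without both MP libraries numbered 1, and 0 to 446 with single libraries left out. In polysomal RNA (551 genes) it was 1558 with no filter, 1624 with DESeq2's Wald test, 304 with the compared groups only, 1825 with 1 surrogate variable, 0 without both MP libraries numbered 1, 197 without both LSK libraries numbered 2, and 0 to 516 with single libraries left out. For polysomal over total RNA in LSK (0 genes by edgeR, 1981 at an unadjusted p under 0.05) it was 547 with no filter, 433 with DESeq2's Wald test, 7 with 1 surrogate variable and 486 with the transformed values. In MP (0 genes by edgeR, 1243 unadjusted) it was 22 with no filter, 30 with DESeq2's Wald test and 1 with 1 surrogate variable, and for the interaction (0 genes by edgeR, 869 unadjusted) 4 with no filter and 1 with DESeq2's Wald test. Other settings stayed within 1.5 times, apart from the block below. The planned fit on the logarithm of the normalized table and the removal of mitochondrial genes were not run. At this depth 31054 of 47480 names had too few counts to be tested. A lone library left in a group was assumed to vary like the others. The no-filter counts test 31421 genes in place of 16426, and otherwise the cause was not tested.

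With the library number as a block the counts were 570 in total RNA and 418 in polysomal RNA, and 1 for polysomal over total RNA in MP when blocked within population. Deviations from group means correlated at −0.37 to 0.62 over 12 same-numbered pairs, 9 of them over 0.1, and 5 of 9 libraries had their best match at their own number. In a group of 2 libraries the deviations are mirror images. Between such groups the pairs numbered 1 and those numbered 2 thus share their value by construction (0.46, 0.25 and 0.59), and these counts overstate the separate evidence. The 6 pairs numbered 1 were at 0.25 to 0.62, the 3 pairs not over 0.1 all held MP polysomal 2, and MP polysomal 3 went with libraries numbered 2 (0.57 to 0.61). This hints at sets shared across groups. The labels do not say which libraries share a lysate or sort, and not every pair went together, so the number was not taken as a pairing.

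Of 145 list tests, 69 were called with the preset correlation, 2 with an estimated one and 16 by fry. Of the 69, 68 kept their call with DESeq2's size factors, 65 with 1 surrogate variable, 64 with the GC trend removed, 58 with the block, 62 without both MP libraries numbered 1, 58 without both LSK libraries numbered 2 and 57 to 66 with single libraries left out. With the block, 11 calls no longer passed, which is not read as a weaker effect. They were T and NK cells (adjusted p = 0.076), macrophages (0.12) and histones (0.46) in polysomal RNA, S phase in MP (0.051), and for the interaction granulocyte progenitors (0.38), neutrophils (0.19), macrophages (0.13), stroma (0.11), ribosomal proteins (0.17), other oligopyrimidine messages (0.30) and the proteasome (0.076). The neutrophil list in total RNA turned to the opposite sign without both MP libraries numbered 1 (adjusted p = 0.85; 2.9e-10 to 0.96 with single libraries left out), and ribosomal proteins in LSK without both LSK libraries numbered 2 (0.57). With single libraries left out, the adjusted p of histones in LSK ran from 1.2e-11 to 0.95 and that of the neutrophil list for the interaction from 3.5e-14 to 0.48, each with the sign turned at its highest value. The cause was not tested.

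The correlation of changes between total and polysomal RNA (0.588) was 0.314 with no filter and 0.314 to 0.62 with single libraries left out. Scaling by library totals moved the median of all genes to −0.36 in total RNA, −0.14 in polysomal RNA, −0.36 in LSK, −0.22 in MP and 0.14 for the interaction.

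Signs of genes that did not pass turned as follows, and the cause was not tested. Kit in total RNA (−0.579) was 0.12 with 1 surrogate variable and −1.28 to 0.834 with single libraries left out. Kit in polysomal RNA (0.133) was −0.0391 with library totals, −0.466 without both LSK libraries numbered 2 and −0.463 to 1.29 with single libraries left out. For the interaction, Mtor was 0.111 with library totals, 0.0595 with the 10 most abundant genes removed, 0.447 with the GC trend removed, 0.175 without both MP libraries numbered 1 and −0.54 to 0.496 with single libraries left out. Rptor was 0.00326 with DESeq2's size factors, 0.216 with library totals, 0.0033 with DESeq2's Wald test, 0.136 with the 10 most abundant genes removed, 0.136 with 1 surrogate variable, 0.691 with the GC trend removed, 0.0487 and 0.444 without both MP libraries numbered 1 and both LSK libraries numbered 2, and −0.431 to 0.298 with single libraries left out. Eif4ebp1 ran from −3.72 to 1.26.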

Other observations

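The tests of plasma cell genes, of genes with a low baseline, of variable genes and of depth in this part were chosen only after the results were seen, and the others were written before. Selp, Meis1 and Spic were also lower in MP polysomal RNA. Selp, which encodes P-selectin of platelets and endothelium, averaged 85.3 ± 34.2 CPM in LSK (n = 2) and 9.46 ± 1.88 CPM in MP (n = 3, log2 change −3.17, SE 0.498, adjusted p = 0.015 by edgeR). The transcription factor gene Meis1 averaged 330 ± 230 and 60.0 ± 13.5 CPM (log2 change −2.46, SE 0.549, adjusted p = 0.0436), and Spic, a macrophage transcription factor gene, 7.15 ± 3.65 and 0.701 ± 0.402 CPM (log2 change −3.34, SE 0.715, adjusted p = 0.0386). All these calls were lost without MP polysomal 1 or MP polysomal 2. Among the higher genes were Acsl6, a fatty acid activating enzyme gene, at 4.34 (SE 0.676, adjusted p = 0.015) and Tspo2, an erythroid cholesterol transport gene, at 2.92 (SE 0.507, adjusted p = 0.0204). In total RNA, Trim10, a gene of erythroid maturation, changed by 4.32 (SE 0.704, adjusted p = 0.0327). The megakaryocyte and platelet list was not called in any comparison, with medians of −0.36 in total RNA (adjusted p = 0.23) and −0.57 in polysomal RNA (adjusted p = 0.41).

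Immunoglobulin transcripts were seen in the LSK libraries, summing to 5780 and 5710 CPM in the total and polysomal libraries numbered 2, 773 and 1030 CPM in those numbered 1, and 161 to 330 CPM in MP, a ratio of number 2 to number 1 of 6.38 within LSK. B cells as the source of the difference between these libraries are argued against, since 12 B cell genes had a ratio of 0.863 and since the 10 left after 2 with a high baseline (97.6% of the MP sum) had a ratio of 1.42, at 9.93 to 15.9 CPM in LSK and at least 299 counts, and unrearranged constant regions too, since at least 29 variable genes had over 10 counts in every LSK library. For 12 plasma cell genes the ratio was 4.02, while the LSK mean of 471 CPM was not above every MP library (up to 837 CPM), which decides nothing because 5 of the 12 genes have a high baseline and make up 99.2% of the MP sum. The other 7 had a ratio of 4.23, with 18.3, 96.1, 11.1 and 28.6 CPM in LSK polysomal 1, LSK polysomal 2, LSK total 1 and LSK total 2 and 2.29 to 5.45 CPM in MP, but Sdc1 alone made up 72.7 of the 96.1 CPM, and the 6 genes without it had a ratio of 2.24. Of the 7 genes with a low baseline, 6 were higher in both LSK libraries numbered 2 than in both numbered 1, and Prdm1 was not. Plasma cells among the sorted cells, which a lineage gate may not fully remove, may be a source. They cannot be told apart from other sources, since Sdc1 makes up most of the summed rise and the other genes are at low levels. The source of the lower immunoglobulin level in the libraries numbered 1 stays open.

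The libraries of each group also split along a shared direction, with 60.3% of the variance within groups on the first component. Over genes with known GC content the share was 60.4%, and it was 57% with the GC trend of each library removed. That removal lowered the sum of squares within groups from 73650 to 60520. Deviations from the group mean correlated with GC content at −0.54 in LSK polysomal 1 and 0.54 in LSK polysomal 2. Total counts differed by at most 1.07 times within a group. These values argue against a smooth GC trend and depth as the whole cause, while GC content may be a part of it. The share on the first component was 60.8% without 506 genes that are in the neutrophil list or follow it. These hold 2.85% of the variance, so the share could not have fallen under 59.2% and maturing neutrophils cannot be told apart from other causes. A difference between sorts, animals or library batches may be behind the split and was not tested, since the labels give none.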
